A study of Mus musculus with 3 samples.

How the data were processed

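Mouse corneal RNA was measured by sequencing in 3 libraries, 1 each from a sham-operated group, a group with the lacrimal gland excised and a group given PNU-282987 eyedrops. Per the labels' protocols, RNA was extracted with TRIzol, its purity was read on a NanoDrop instrument and its integrity on a Bioanalyzer, and libraries were made with the VAHTS Universal V6 kit. The authors deposited 1 table of whole-number counts of reads per gene, and the counts were used as deposited. The submitters' processing notes name HTSeq and R 3.2.0. The aligner, the genome build, the annotation, the strand setting and how reads shared between similar genes were counted are not given in the sources used here, so no coordinates are printed. Genes with near-identical copies, overlapping genes and antisense genes can exchange reads under such counting, and are reported with that limit. The sample of each column was read from its name, which matches the sample's title, and its group from the treatment label.

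The table held 21760 genes, 16787 of them protein coding and 4973 non-coding, and 0 rows without a count in any library. Total counts were 37703843 for sham, 37692972 for excision and 39616004 for PNU-282987, and 19419, 19665 and 19033 genes had a count. The 10 most abundant genes took 16.0%, 14.2% and 16.9% of the counts. Across 12723 genes with at least 20 counts in each library, log2 CPM (counts scaled to library size) correlated with r = 0.974 for excision and sham, 0.984 for PNU-282987 and sham and 0.974 for PNU-282987 and excision. A count of 0 allows up to 3 counts, which is 0.0768, 0.0808 and 0.0773 CPM in sham, excision and PNU-282987. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

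Counts were scaled with TMM factors from edgeR 4.0.16 in R 4.3.3, which were 1.04 for sham, 0.985 for excision and 0.980 for PNU-282987 relative to the totals. The remaining steps ran in Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and the plots in matplotlib 3.10.9. Genes with at least 20 counts in at least 1 library were kept, which left 14180. For each of the 3 comparisons a gene's ratio of scaled counts was computed with nothing added. A count of 0 was set to the floor of 3 counts per library, which makes the fold a lower bound, and no ratio was given where the other library also had 3 counts or fewer. The 95% interval of a ratio was the exact conditional binomial (Clopper-Pearson) interval of the 2 counts. A gene was counted as higher or lower when the ratio was at least 2-fold and the interval excluded equal levels. With 1 library per group there was no model of the spread between animals, so no p-values were computed, and a ratio compares 2 libraries, not 2 conditions.

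The scheme was tested on simulated counts drawn from the sham counts of genes with at least 20 counts there. Over 13565 genes, 66 were given a 4-fold, 65 a 3-fold and 66 a 2-fold difference in the simulated excision library. Genes near 0 in sham were not among them, so the scheme was not tested on such genes. It called 100% of the 4-fold genes, 100% of the 3-fold genes, 56.1% of the 2-fold genes and 0.11% of the unchanged genes, with counting noise as the only noise. The interval held the true ratio for 98.5%, 98.5%, 93.9% and 95.4% of them.

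Lists of genes for pathways, corneal cell types and tissues that a corneal sample could carry along were fixed, 47 in all, with the comparisons, thresholds and named-gene rule before the data were examined. For a list with at least 5 members that had a ratio, the median log2 ratio was compared with the medians of 10000 random lists of the same size matched on mean expression in 20 bins. A list was said to stand apart below percentile 2.5 or above percentile 97.5. Of 128 list and comparison pairs with a percentile, 68 stood apart where 6.4 would by chance, although genes of a list vary together, so that the percentile is not an error rate. Members at 0 in one library entered the median at their bound.

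Genes named in the text follow a fixed rule. They are the 10 genes with the largest ratio in each direction per comparison among called genes with at least 100 counts in the higher library, leaving out gene models, pseudogenes and immune receptor segments. For each list they are the 4 called members with the largest ratio, and 12 genes tied to the study's question were to be named whatever their values, of which 11 were named and Il6 was not analysed here. Ifnl3, Ddx58, Lyz2, Ptprc, Krt7, Krt13 and Krt19 were named after their values were seen. Some genes that meet the rule are not reported here.

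Because comparisons share a library, libraries without any group difference were simulated from the mean levels with an added spread of 0, 0.2 or 0.4 (coefficient of variation), 10 times each, and analysed in the same way. For excision against sham they gave 19.9, 212 and 1762 genes called higher and 21.5, 222 and 1741 called lower at the 3 spreads, so calls among unchanged genes depend on a spread that was not measured. The alternatives were DESeq2 1.42.0 size factors, upper-quartile factors and total counts in place of TMM, count minimums of 10, 50 and none, a fold minimum of 4 or 1.5, 2 counts added before the ratio, thinning to the smallest library, and for lists the mean or 10 bins. Leaving out the tissue lists was added after the data were seen.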

Results

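RNA was sequenced from mouse cornea, the transparent front of the eye, in 3 libraries with 1 library per group. The sham group had an incision near the lacrimal glands that left the glands in place. The excision group had the tear-producing lacrimal gland removed, a surgical model of dry eye. The PNU-282987 group received eyedrops of PNU-282987, an agonist of the α7 nicotinic acetylcholine receptor, 3 times a day, and the labels do not say whether these mice had also lost the gland, or whether corneas of several mice were pooled in a library. The study asked what the α7 receptor does in dry eye disease. Total gene counts were 37703843 for sham, 37692972 for excision and 39616004 for PNU-282987, over a table of 21760 genes. The groups had no replicates, so no difference could be set against the spread between animals, no test was made, and every comparison below is between libraries. Each fold is given with its 95% counting interval, which covers counting error only. A gene was counted as higher or lower when its ratio was at least 2-fold and that interval excluded equal levels. Gene list medians are log2 ratios, and their place among 10000 random lists of the same size and expression is a description of these libraries.

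The receptor under study was near the detection limit. Chrna7 (gene ID 11441), which encodes the α7 subunit, had 11 counts in sham, 2 in excision and 9 in PNU-282987. The excision library was 5.23-fold lower than sham (95% interval 1.14 to 48.5), on counts below the minimum used for the gene totals, and PNU-282987 against excision was not distinguishable at this depth (4.30-fold higher, 0.890 to 40.9). Of the nicotinic subunit genes, 13 were in the table and 3 were measured. Among these, Chrnb3 had 62, 9 and 30 counts in sham, excision and PNU-282987, and Chrnb2 had 24, 52 and 31. Of the other cholinergic genes, the muscarinic receptor gene Chrm1 (27, 4 and 22 counts) and Ache, the enzyme that breaks down acetylcholine (32, 6 and 22 counts), were lower in excision than in both other libraries. Ric3, a chaperone of nicotinic receptors, had 83, 38 and 59 counts. Ly6e, a gene of the Ly6 family, was higher than in sham in both, at 10561, 26267 and 23478 counts (2.62-fold in excision, 2.56 to 2.68, and 2.24-fold in PNU-282987, 2.185 to 2.288). The list median of these other cholinergic genes was near 0 in all 3 comparisons, at -0.02 for excision against sham, 0.21 for PNU-282987 against excision and -0.06 for PNU-282987 against sham. Lens and retina transcripts, described below, were also lowest in the excision library (the lens gene Cryaa had 9525, 175 and 8774 counts). Whether the cholinergic genes that were lower in excision came from such tissue was not tested.

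The comparison of excision with sham addressed what differs in a cornea after loss of the gland. The excision library held far more transcript from interferon-stimulated genes, which encode antiviral effectors: 28 of 29 measured members were higher than in sham, none was lower, and the list median was 1.93, above all 10000 random lists. Ifi27l2a (gene ID 76933), an interferon-induced gene, had 370 counts in sham and 13664 in excision (38.9-fold higher, 35.0 to 43.2). Cmpk2 (gene ID 22169) was 13.8-fold higher (11.4 to 16.8), Rsad2 (gene ID 58185), which encodes the antiviral enzyme viperin, was 12.4-fold higher (10.6 to 14.6), and Oas2 (gene ID 246728), a sensor of double-stranded RNA, was 11.8-fold higher (10.97 to 12.7). Ddx58 was the member that did not reach 2-fold, with a log2 ratio of 0.54. In the same library lens transcripts were lower (list median -4.88), as were red blood cell transcripts (-2.08).

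Genes outside that list that led the comparison included further interferon-inducible families. Slfn5 (gene ID 327978) of the Schlafen family had 4 counts in sham and 370 in excision (97.3-fold higher, 37.7 to 359.0). Nlrc5 (gene ID 434341), a transactivator of MHC class I genes, was 39.6-fold higher (22.9 to 74.9), and the class I-like gene H2-T24 was 38.2-fold higher (12.7 to 188). Slfn1 was 20.5-fold higher (10.2 to 48.4), Gvin2 20.3-fold (9.07 to 56.6) and Ifi203 16.6-fold (11.9 to 23.8). The GTPase genes Tgtp2 (125-fold, 22.0 to 4986) and Tgtp1 (62.6-fold, 24.1 to 232) are near-identical copies, so the split of reads between them is uncertain. Ifnl2 (gene ID 330496), an interferon lambda gene, had 0 counts in sham, 101 in excision and 0 in PNU-282987, so it was at least 35.4-fold higher against a floor of 3 counts per library. Its near-identical neighbour Ifnl3, named after its values were seen, had 0, 82 and 0 counts, and reads could be split between the pair.

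Immune cell transcripts were also higher in the excision library, at low absolute levels. For MHC class II presentation, used by antigen-presenting cells, 5 of 8 measured genes were higher and none lower (list median 2.49, above all random lists). Cd74 (gene ID 16149), the class II invariant chain, had 282 counts in sham and 2297 in excision (8.57-fold higher, 7.57 to 9.73), and H2-Eb1 (8.57-fold, 7.08 to 10.4), H2-Ab1 (8.24-fold, 6.64 to 10.3) and H2-Aa (7.22-fold, 5.93 to 8.85) were close to it. Macrophage and monocyte markers had 8 of 19 members higher and none lower (median 0.83, above all random lists), led by Lyve1 with 2 and 23 counts, Fcer1g with 17 and 69, C1qa with 80 and 260, and C1qb with 82 and 249. T and NK cell markers had 5 of 6 measured members higher (median 3.01, above all random lists), out of 16 in the table. Among these Gzma, a killer-cell protease, had 3 and 82 counts, Nkg7 had 4 and 25, Cd8a had 0 and 37 (at least 13.0-fold higher) and Cd3g had 0 and 28 (at least 9.82-fold higher). Each of these named genes passed the count minimum only through excision. The filter thus partly fixed a high median for this list, and no conclusion is drawn from its place among random lists. The dendritic cell list did not stand apart (median 0.16), although Itgax (7 and 33 counts) and Irf8 (46 and 102 counts) were higher. Of its 15 genes 5 were measured. Nearly all of its summed level (585 CPM in sham and 408 CPM in excision) came from members other than Itgax and Irf8. Whether the transcripts of those members came from dendritic cells was not tested. In the same library the vascular and lymphatic list (median 0.95) and the conjunctival and gland list (0.61) were also above sham by their medians. The summed level of the vascular list went the other way. Whether the immune cell transcripts came with other tissue in the sample was not tested.

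For the macrophage genes chosen in advance, excision against sham gave 1.78-fold higher Cd68 (494 and 834 counts; interval 1.59 to 1.99) and 1.77-fold higher Adgre1 (22 and 37 counts; 1.02 to 3.15), both under 2-fold. Classical, M1-type genes went both ways (median -0.13 and mean 0.73): Cxcl9, a chemokine for T cells, had 1 and 29 counts and Ccl5 had 5 and 73, whereas the inflammatory cytokine Tnf was 2.20-fold lower (816 and 352 counts; 1.94 to 2.504) and Ptgs2 was 2.24-fold lower (1.24 to 4.21). Nos2 had 6 and 16 counts, and Il1b had 10 and 12. Alternative, M2-type genes had a median of 0.64 with 2 of 9 members higher and 1 lower. Retnla had 0 and 34 counts (at least 11.9-fold higher), the mannose receptor gene Mrc1 had 6 and 33 (5.79-fold higher, 2.39 to 16.9), Chil3 had 58 and 18 (3.06-fold lower, 1.78 to 5.52), and Arg1 was within 2-fold at 9388 and 10958. Arg1 counts were far above those of Adgre1, Cd68 and Mrc1, and whether they came from macrophages was not tested. Il6 was not analysed here.

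Neutrophil and NF-kB-linked transcripts were lower in excision than in sham. Of 11 measured neutrophil markers 7 were lower and 1 higher (median -2.12, below all random lists). S100a9 (gene ID 20202), a calcium-binding alarmin, had 718 counts in sham and 34 in excision (20.1-fold lower, 14.2 to 29.2), Camp had 74 and 9, Cd177 had 70 and 10, and Ngp had 34 and 6. NF-kB response genes had 5 of 23 members lower and none higher (median -0.42, below all random lists). The neutrophil-attracting chemokine genes Cxcl2 (225 and 19 counts, 11.3-fold lower, 7.04 to 19.1) and Cxcl1 (100 and 13 counts, 7.31-fold lower, 4.09 to 14.2) led them. Red blood cell transcripts, a sign of blood in the sample, were lower beside these lists: Hbb-bs had 1291 counts in sham and 224 in excision, and Hba-a1 had 612 and 122, with reads possibly shared among the haemoglobin copies.

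**Figure D1:**
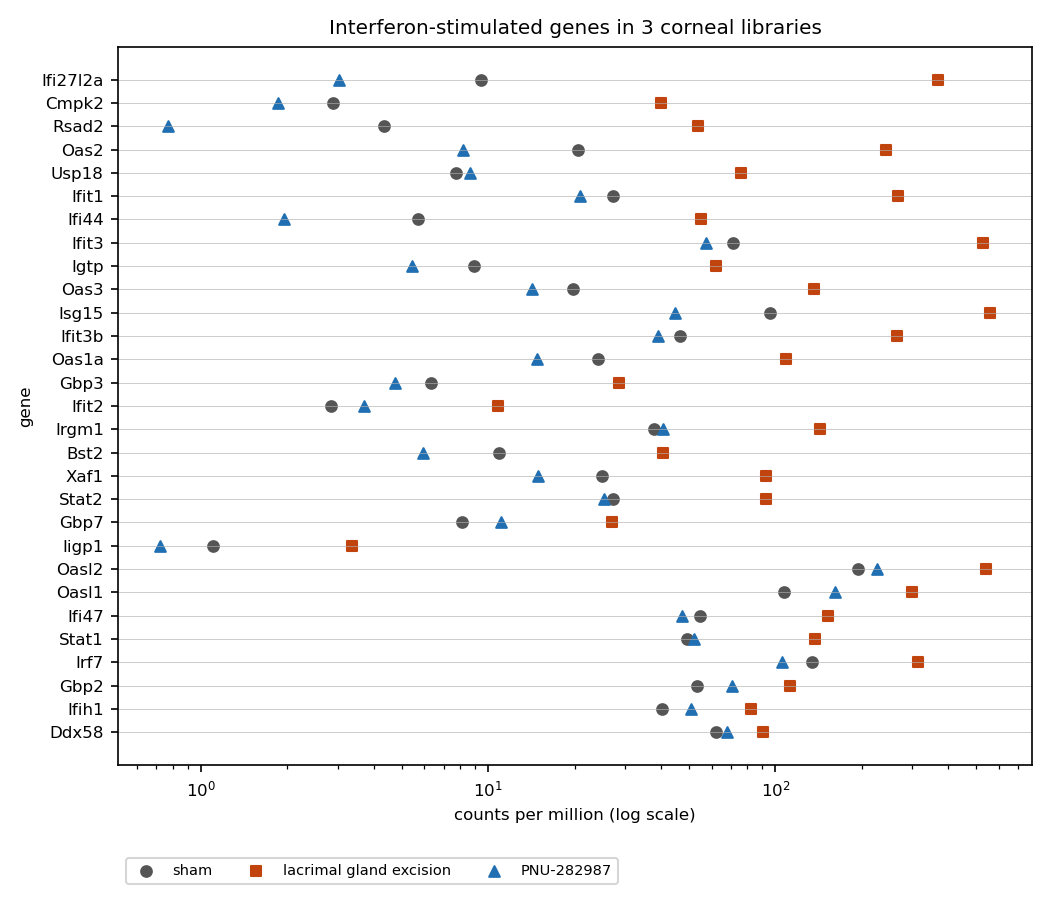
CPM (counts scaled to library size, log scale, horizontal axis) of the 29 measured interferon-stimulated genes (vertical axis) in the sham (circles), lacrimal gland excision (squares) and PNU-282987 (triangles) libraries, with 1 library per group and no error bars. The excision library lies to the right of both others for each of these genes, and Ifi27l2a has 13664 counts there against 370 in sham and 118 in PNU-282987.

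Transcripts of lens, retina and corneal endothelium were lower in the excision library than in sham. Of 19 measured lens genes, 18 were lower (median -4.88, below all random lists): the β-crystallin gene Crybb1 (gene ID 12960) had 504 and 3 counts (160-fold lower, 54.3 to 777), Crygd (gene ID 12967) 839 and 6 (133-fold, 60.8 to 363), Crygs (gene ID 12970) 2021 and 21 (91.5-fold, 59.7 to 148) and Cryba2 1057 and 11 (91.3-fold, 50.8 to 184). Cryaa, the major lens chaperone, had 9525 and 175 counts, and the γ-crystallin genes resemble one another closely enough to share reads. Retina genes were lower in 8 of 12 cases (median -1.69), with Prph2 at 56 and 7 counts, Gngt1 at 29 and 4, and Nrl at 15 and 3. Corneal endothelial markers, from the inner cell layer that keeps the cornea dehydrated, were lower in 11 of 14 and higher in 1 (median -1.80, below all random lists). Col8a1, a collagen of Descemet's membrane, was 7.09-fold lower (6.24 to 8.07), the bicarbonate transporter gene Slc4a4 5.65-fold lower (4.83 to 6.63), Cdh2 5.61-fold lower (4.18 to 7.66) and Atp1b1 5.45-fold lower (5.04 to 5.90).

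Stromal genes were lower by less. Of 23 keratocyte and stromal matrix genes, 7 were lower and none higher (median -0.62, below all random lists): Thbd was 4.57-fold lower (3.87 to 5.42), Smoc1 4.01-fold (3.52 to 4.59), the small proteoglycan gene Ogn 3.55-fold (3.17 to 3.98) and Chst5, a sulfotransferase for keratan sulfate, 3.43-fold (3.15 to 3.75). Myofibroblast and fibrotic matrix genes had 6 of 20 lower and 1 higher (median -0.46). Of these Cthrc1 had 475 and 104 counts, Loxl2 326 and 91 and Myl9 675 and 197, while tenascin C (Tnc) was higher at 22 and 70. These lists were lower in the same library in which lens and endothelial transcripts were lower.

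Corneal epithelial identity did not stand apart between excision and sham (median 0.10, with 1 of 24 genes higher and none lower). Krt12, the cornea-specific keratin, was 1.29-fold lower (1.288 to 1.294) and the eye-field transcription factor gene Pax6 was 1.04-fold lower (1.02 to 1.06). The basal and limbal keratin gene Krt15 was 2.20-fold higher (2.18 to 2.22). Wound-response keratins and migration genes had 5 of 26 members higher and 4 lower (median 0.26, percentile 99.88): the protease inhibitor genes Serpinb2 (3 and 18 counts) and Serpinb3a (5.38-fold higher, 4.70 to 6.17) and the keratin genes Krt4 (4.94-fold, 4.75 to 5.14) and Krt17 (4.49-fold, 3.57 to 5.69) led it. The conjunctival and gland list, which also holds Krt4, had 4 of 14 higher and 1 lower in the same comparison (median 0.61, above all random lists), with Muc5ac (1 and 11 counts) and Agr2 (49 and 133) higher and Fa2h (20 and 3) lower. Mucin and glycocalyx genes had 4 of 15 higher and 1 lower (median 0.30), with Muc1, a membrane mucin, 4.36-fold higher (3.98 to 4.78). In the cornified envelope list the late cornified envelope genes Lce3b (205 and 12 counts), Lce3f (50 and 3) and Lce3a (3297 and 825) were lower, although the list median was 0.06 (-0.016 when scaled to total counts) and its mean was -0.45. These Lce3 genes resemble one another and may share reads.

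Between excision and sham, nerve-linked genes differed singly, in lists that did not stand apart. The neuronal and axonal list (5 measured) had a median of 0.81 and did not stand apart: Thy1, also a T cell marker, had 9 and 111 counts, P2rx3, a channel of sensory neurons, had 18 and 47, and Uchl1 had 41 and 17. Neurotrophic factor and neuropeptide receptor genes had a median of -0.21 with 6 of 24 lower and 2 higher. The axon guidance gene Slit2 was 7.59-fold lower (942 and 118 counts; 6.26 to 9.27), the GDNF receptor gene Gfra1 4.75-fold lower (3.97 to 5.71), and Bdnf (12 and 2 counts) was lower. Schwann cell genes had a median of 0.22 and a single member past 2-fold, Ncam1 (2.94-fold lower, 2.49 to 3.49). The corneal endothelial and lens lists were lower in the same library (medians -1.80 and -4.88). Whether Slit2, Gfra1, Bdnf and Ncam1 were lower along with that tissue was not tested.

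In total, 568 genes were higher and 777 lower in excision than in sham, of 14180 measured. Without the members of the lens, retina, endothelial, conjunctival, mucin, red blood cell and neutrophil lists, an alternative added after the data were seen, these were 560 and 727. Simulated libraries with no group difference gave on average 19.9 higher and 21.5 lower genes with counting noise alone, 212 and 222 with an added spread between libraries of 0.2 (coefficient of variation), and 1762 and 1741 with 0.4, more than were observed. The spread between corneas of a group was not measured, so how many of the observed genes it would give is open.

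PNU-282987 against excision addressed what differs in a cornea given the agonist from one after gland loss. Interferon-stimulated genes were lower in PNU-282987 for 25 of 29 members and higher for none (median -2.63, below all random lists). Ifi27l2a was 121-fold lower (101 to 147), Rsad2 69.9-fold lower (48.8 to 104), Oas2 29.6-fold lower (26.5 to 33.2) and Ifi44 28.1-fold lower (22.3 to 35.8). Slfn4 (gene ID 20558) was 75.5-fold lower (60.3 to 95.8), Nlrc5 51.1-fold lower (27.6 to 107), and Apol9b (gene ID 71898), whose reads could be shared with Apol9a, 44.5-fold lower (35.5 to 56.5). Tgtp2 and Tgtp1 were lower by 124-fold (21.9 to 4958) and 35.6-fold (17.0 to 89.4), again with the split between copies uncertain. Ifnl2 was at least 35.2-fold lower. The PNU-282987 library also held more lens (list median 4.84) and retina transcript (2.75) than the excision library.

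Secretory and goblet cell transcripts were a second large difference, higher in the PNU-282987 library. Muc5ac (gene ID 17833), the gel-forming mucin of conjunctival goblet cells, had 1 count in sham, 11 in excision and 2980 in PNU-282987 (259-fold higher than excision, 144 to 519). Gp2 (gene ID 67133), a glycoprotein gene of secretory epithelia, had 5, 4 and 3801 counts (908-fold higher than excision, 354 to 3336). Muc5b, a second gel-forming mucin, had 1, 0 and 676 counts and was at least 215-fold higher. The secretoglobin genes Scgb2b2 (0, 0 and 768 counts) and Scgb1b2 (0, 0 and 186) were at least 245-fold and at least 59.3-fold higher, and Esp6, of the exocrine gland-secreted peptides, had 0, 1 and 259 counts (248-fold, 44.0 to 9816). The mucin list had 6 of 15 members higher and 1 lower (median 0.25, percentile 97.74, and 97.38 with 10 expression bins, where it did not stand apart), although its summed level was 4569 CPM in excision and 3077 CPM in PNU-282987. The members higher in PNU-282987 included the membrane mucin Muc16 with 1 and 54 counts and the trefoil factor gene Tff1 with 4 and 96. The conjunctival and gland list, which shares Muc5ac, Muc5b and Agr2 with it, had 4 of 14 higher and 1 lower (median 0.54, percentile 99.99). Agr2, a goblet cell protein-folding gene, was 13.1-fold higher (10.9 to 15.7).

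**Figure D2:**
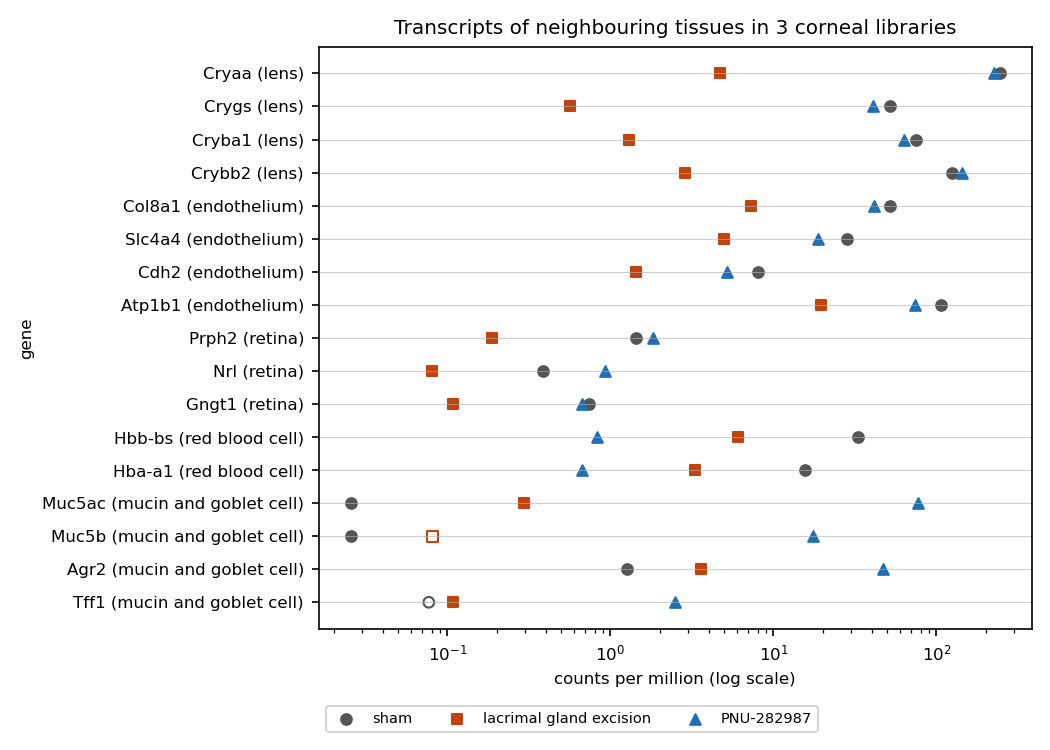
CPM (counts scaled to library size, log scale, horizontal axis) of genes typical of lens, corneal endothelium, retina, red blood cells, and mucin or goblet cells (vertical axis) in the 3 libraries, with 1 library per group and no error bars; open symbols are counts of 0 drawn at the floor of 3 counts. Cryaa has 175 counts in the excision library against 9525 in sham and 8774 in PNU-282987, and Muc5ac has 2980 counts in PNU-282987 against 1 in sham and 11 in excision.

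MHC class II, macrophage, and T and NK cell transcripts were lower in PNU-282987 than in excision. MHC class II genes were lower for 7 of 8 (median -1.44, below all random lists), with Cd74 4.07-fold lower (3.71 to 4.46), H2-Eb1 4.01-fold (3.48 to 4.62), H2-Ab1 3.77-fold (3.23 to 4.43) and H2-Aa 2.77-fold (2.42 to 3.17). Macrophage and monocyte markers were lower for 9 of 19 (median -0.97, below all random lists): Lyve1 had 23 counts in excision and 1 in PNU-282987, the monocyte gene Ly6c2 had 26 and 5, C1qb was 3.62-fold lower (2.77 to 4.77) and Fcgr3 3.38-fold lower (2.15 to 5.47). T and NK cell markers were lower for 4 of 6 (median -2.50), with Cd8a at 37 and 1 counts, Cd3g at 28 and 0, Gzma at 82 and 14 and Nkg7 at 25 and 5. These genes passed the count minimum only through excision. Dendritic cell markers did not stand apart (median 0.28 and mean -0.02, 4 of 5 above 0), with Itgax lower (33 and 11 counts), and the chemokine gene Cxcl17 was 41.5-fold higher (5 and 217 counts; 17.5 to 129). Cd68 (1.17-fold lower, 1.06 to 1.29) and Adgre1 (37 and 23 counts; 1.68-fold lower, 0.974 to 2.97) were within 2-fold. Mrc1 was 11.5-fold lower (33 and 3 counts; 3.61 to 58.6), Retnla at least 11.9-fold lower, Stab1 3.04-fold lower (2.03 to 4.67), Ccl5 38.2-fold lower (73 and 2 counts; 10.2 to 321) and Cxcl9 at least 10.1-fold lower. Tnf was not distinguishable between these libraries (352 and 337 counts), Nos2 had 16 and 8 counts, Il1b had 12 and 2 (6.28-fold lower, 1.40 to 57.7), and Arg1 was 1.06-fold higher (1.04 to 1.09).

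Complement genes, a list that shares C1qa, C1qb and C1qc with the macrophage list, were lower for 3 of 17 and higher for 1 in PNU-282987 than in excision (median -0.42, percentile 0.73). With the mean the complement list did not stand apart (percentile 6.8), and its summed level was 295 CPM in excision and 356 CPM in PNU-282987. C4b had 44 and 9 counts, C1qb and C1qc were lower, and Cd59a, an inhibitor of the membrane attack complex, was 2.23-fold higher (1.94 to 2.57). NF-kB response genes had 4 of 23 higher and none lower (median 0.10), led by the adhesion molecule gene Icam1 (41 and 138 counts, 3.22-fold higher, 2.26 to 4.68) and Tnfaip2 (2.63-fold, 2.07 to 3.37). Cxcl1 and Cxcl2 had 12 and 22 counts in PNU-282987, close to their 13 and 19 in excision. JAK2-STAT3 genes did not stand apart (median -0.16), with the acute-phase gene Lbp (40 and 10 counts) and the feedback inhibitor genes Socs1 (141 and 43) and Socs3 (29 and 13) lower. S100a9 was 17.3-fold higher (34 and 617 counts; 12.3 to 25.3), while the neutrophil list had a median of 0.24 and did not stand apart. Of the haemoglobin transcripts, Hbb-bs (224 and 32 counts), Hba-a1 (122 and 26) and Hba-a2 (64 and 25) were lower than in excision, and Hbb-bt had 16 counts in both. The red blood cell list stood apart as lower (median -0.74, percentile 0.16). Its summed level was 33.7 CPM in excision and 36.9 CPM in PNU-282987, most of it from members other than these haemoglobin genes.

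Lens genes were higher in PNU-282987 than in excision for 16 of 19 and lower for none. Crybb1 was 126-fold higher (42.9 to 614), Cryba2 83.4-fold (46.4 to 168), Crygs 71.9-fold (46.9 to 116), Crybb2 49.98-fold (41.2 to 61.2) and Lgsn, a lens protein gene, 79.8-fold (21.8 to 664). Retina genes were higher for 11 of 12, with Rbp3 at 8 and 85 counts. Corneal endothelial markers were higher for 9 of 14 (median 1.36, above all random lists): Col8a1 by 5.63-fold (4.95 to 6.43), Slc4a4 by 3.79-fold (3.22 to 4.47), Atp1b1 by 3.73-fold (3.44 to 4.06) and Cdh2 by 3.62-fold (2.67 to 5.004). Keratocyte genes had 4 of 23 higher (median 0.11, not standing apart), led by Ogn at 2.67-fold (2.38 to 3.01) and Thbd at 2.39-fold (2.001 to 2.88).

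In the epithelium, corneal identity genes had no member past 2-fold (median -0.001), and Krt12 (1.38-fold higher, 1.37 to 1.38) and Pax6 (1.03-fold higher, 1.01 to 1.05) were close to equal. The stress keratin gene Krt16 was 7.47-fold higher (326 and 2546 counts; 6.65 to 8.40) and Krt18 2.90-fold higher (2.34 to 3.62). Cell cycle genes were lower as a list without any member past 2-fold (median -0.33, 25 of 28 below 0, below all random lists). Immediate early genes, which respond within minutes to stimulation, had 20 of 22 members below 0 and 3 past 2-fold (median -0.40, percentile 0.01), with Atf3 4.34-fold (3.06 to 6.29), Fosb 4.32-fold (3.36 to 5.62) and the phosphatase gene Dusp1 2.01-fold lower (1.91 to 2.12). This list was above sham in excision (median 0.35, percentile 99.99) and below sham by less in PNU-282987 (median -0.13, percentile 0.65). Among nerve-linked genes, Bdnf had 2 and 25 counts, Slit2 was 3.00-fold higher (2.44 to 3.73), Thy1 6.83-fold lower (4.08 to 12.1) and the mechanosensitive channel gene Piezo2 2.49-fold lower (1998 and 838 counts; 2.30 to 2.71).

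In total, 553 genes were higher and 797 lower in PNU-282987 than in excision, and 508 and 792 without the tissue lists named above. The simulated libraries with no difference gave 21.3 and 18.4, 217 and 219, and 1735 and 1752 at the same 3 spreads. Since the labels leave open whether the PNU-282987 mice had lost the gland, these libraries may differ by the surgery as well as by the eyedrops.

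PNU-282987 against sham addressed how far the library given the agonist lay from sham. The secretory genes led again: Muc5ac was 2997-fold higher (1 and 2980 counts; 538 to 118400), Gp2 764-fold (327 to 2356), Muc5b 680-fold (122 to 26890), Scgb2b2 at least 258-fold and Scgb1b2 at least 62.3-fold, Esp6 at least 86.8-fold, Tff1 at least 32.2-fold and the mucosal chemokine gene Cxcl17 (0 and 217 counts) at least 72.7-fold. The conjunctival and gland list had 7 of 14 members higher and none lower (median 1.01, above all random lists), and the mucin list 7 of 15 (median 0.39, percentile 99.98). Agr2 was 37.3-fold higher (28.1 to 50.6) and Krt4, a keratin of conjunctival and other wet epithelia, 7.22-fold higher (6.95 to 7.51). Krt17 was 9.81-fold (7.92 to 12.3), Serpinb3a 10.8-fold (9.54 to 12.4), Serpinb2 17.4-fold (5.64 to 87.3) and Krt15 3.68-fold (3.65 to 3.71) higher, and each of these was also higher in excision than in sham. Krt12 was 1.07-fold higher (1.06 to 1.07) and Pax6 was not distinguishable (1.01-fold lower, 0.995 to 1.03).

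Interferon-stimulated genes in PNU-282987 were lower than in sham as a list, with 5 of 29 lower and none higher (median -0.35, below all random lists), although 10 of the members lay above 0 and 19 below. Rsad2 was 5.64-fold lower (3.81 to 8.61), Ifi27l2a 3.12-fold (2.53 to 3.87), Ifi44 2.90-fold (2.23 to 3.82) and Oas2 2.51-fold lower (2.21 to 2.87). MHC class II genes were above sham for 4 of 8 (median 1.04, above all random lists), with H2-Aa 2.61-fold (2.10 to 3.26), H2-Ab1 2.18-fold (1.70 to 2.82), H2-Eb1 2.14-fold (1.71 to 2.68) and Cd74 2.11-fold higher (1.83 to 2.44). Macrophage markers did not stand apart (median 0.07 and mean -0.15, and median -0.007 when scaled to total counts), with Ly6c2 7.36-fold lower (37 and 5 counts; 2.88 to 24.0), Fcgr3 2.56-fold lower (1.61 to 4.20) and Cd68 1.52-fold higher (1.35 to 1.71). Classical, M1-type genes had a median of -0.99 with 2 of 8 members, Tnf and Socs3, lower (percentile 0.24, and 2.7 with the mean, where they did not stand apart). Dendritic cell markers had a median of 0.44 over 5 members (percentile 99.0, and 95.37 with the mean, where they did not stand apart), with Irf8 higher at 46 and 111 counts. Nearly all of the summed level of this list again came from members other than Itgax and Irf8, whose source was not tested. Adgre1 (22 and 23 counts), Nos2 (6 and 8) and Mrc1 (6 and 3) were not distinguishable at this depth, Il1b had 10 and 2 counts, and Arg1 was 1.31-fold higher (1.27 to 1.34). Lens transcripts were nearer to sham than in the excision library (median -0.35, 5 of 19 lower), and retina transcripts were higher (median 0.78, 5 of 12 higher).

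Neutrophil, red blood cell, keratocyte and endothelial lists were lower than sham in both other libraries. Neutrophil markers were lower in PNU-282987 for 6 of 11 and higher for none (median -1.41, below all random lists), with the granule genes Mpo (515 and 131 counts; 3.91-fold, 3.22 to 4.77) and Elane (602 and 156 counts; 3.84-fold, 3.21 to 4.61), Camp 8.18-fold (4.08 to 18.6) and Ngp 16.9-fold lower (34 and 2 counts; 4.33 to 145). The NF-kB response list did not stand apart in PNU-282987 against sham (median -0.03, 5 of 23 lower and 2 higher). Its higher members included Nfkbie at 3.25-fold (1.99 to 5.50). Tnf was 2.41-fold lower (2.12 to 2.74), Cxcl2 10.2-fold (6.55 to 16.5), Cxcl1 8.29-fold (4.54 to 16.6), Socs3 3.82-fold (2.05 to 7.67) and the acute-phase gene Hp 4.03-fold lower (2.77 to 6.02). Red blood cell transcripts were lower beside them for 4 of 6 (median -3.64, below all random lists), with Hbb-bs 40.1-fold (28.3 to 58.9) and Hba-a1 23.4-fold lower (15.8 to 36.1). Keratocyte genes had a median of -0.54, with Col5a1 2.20-fold lower (1.97 to 2.45) the single member past 2-fold, and endothelial markers a median of -0.61 with 3 of 14 lower and 1, Car12 (27 and 276 counts), higher. Cell cycle genes did not stand apart in excision against sham (median -0.001), and were lower in PNU-282987 than in sham as a list (median -0.34, 3 of 28 past 2-fold), including the proliferation marker Mki67 (2.27-fold, 2.10 to 2.45) and Cenpf (2.45-fold, 2.15 to 2.81).

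The 3 nerve-linked lists stood apart in PNU-282987 against sham by the median and not by the mean. The neurotrophic list had a median of -0.41 with 4 of 24 lower and 2 higher (percentile 0.09, and 11.48 with the mean), with Vipr1 (36 and 114 counts) higher and Tacr1 (21 and 8), Slit2 (942 and 371) and Sema3a (146 and 62) lower. The Schwann cell list had a median of -0.30 with no member past 2-fold (percentile 1.4, and 16.75 with the mean). The neuronal list, with 5 measured, had a median of 0.745 (percentile 98.86, and 97.44 with the mean), with Snap25 higher (3 and 30 counts) and Piezo2 lower (2099 and 838). Its summed level went the other way, at 55.56 CPM in sham and 24.85 CPM in PNU-282987.

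Casp1 (gene ID 12362), the inflammasome protease, stood out from its list. It had 3 counts in sham, 99 in excision and 196 in PNU-282987, which was 34.7-fold higher in excision than in sham (11.5 to 171) and 65.7-fold higher in PNU-282987 than in sham (22.2 to 321). A strain or genotype difference between the animals at this gene and Casp4 was not tested and counts alone leave it open. Casp4, its neighbour in function, had 3, 19 and 32 counts, and Zbp1, a nucleic acid sensor that interferon induces, had 593, 3798 and 278. The inflammasome list itself did not stand apart by its median in any of the 3 comparisons (0.17, -0.09 and -0.03). By its mean it stood apart in excision against sham (0.97, percentile 99.98) and in PNU-282987 against sham (0.61, percentile 99.71, opposite in sign to the median). Single genes lower in PNU-282987 than in sham included Xlr3a (156 and 2 counts), which has close copies on the X chromosome, the imprinted RNA gene Meg3 (8.03-fold, 4.59 to 15.2), the lactate transporter gene Slc16a3 (6.86-fold, 4.28 to 11.6) and Nxph4 (6.77-fold, 5.05 to 9.24). Rhox4a, one of a family of near-identical homeobox genes, had 2 and 118 counts.

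In total, 366 genes were higher and 703 lower in PNU-282987 than in sham, and 349 and 685 without the tissue lists. The simulated libraries with no difference gave 20.3 and 20.4, 218 and 213, and 1742 and 1738 at the same 3 spreads.

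Set side by side, the excision library was the one that most often lay apart. Of 2258 genes with a range of at least 2-fold, excision stood apart from the other two in 41.5% (938 genes; exact 95% interval 39.5% to 43.6%), PNU-282987 in 30.9% (698 genes; 29.0% to 32.9%) and sham in 27.5% (622 genes; 25.7% to 29.4%). Excision was above both others in 463 of its genes and below both in 475, and PNU-282987 in 198 and 500. In the simulated libraries with no group difference, the largest of the 3 shares averaged 37.4%, 34.7% and 34.02% with an added spread between animals of 0, 0.2 and 0.4 as a coefficient of variation. Both the interval and the simulation treat genes as independent. Genes that vary together in a single sample, such as the lens genes, are not covered by either. Interferon and class II genes such as Ifi27l2a and Cd74 were among those highest in excision, and lens genes such as Cryaa among those lowest.

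The differences of excision from sham and of PNU-282987 from excision were opposed across 14156 genes (Pearson r = -0.644, covariance -0.366), which are not independent replicates. Because both use the excision library, simulated unchanged libraries gave r = -0.508, -0.501 and -0.502 and covariances of -0.018, -0.107 and -0.401 at the same 3 spreads. Of the genes higher in excision than in sham, 313 were also lower in PNU-282987 than in excision, and 345 were lower and then higher. Independent lists of these sizes would share 31.9 and 30.3, and unchanged libraries shared 2.4, 26.7 and 528 in the first direction and 4.1, 52.8 and 721 in the second. The differences of excision and of PNU-282987 from the shared sham library had r = 0.403 and covariance 0.191, against simulated r of 0.495, 0.498 and 0.497 and covariances of 0.018, 0.107 and 0.395. Higher in both than in sham were 150 genes and lower in both 276, against 14.7 and 38.5 for independent lists, and 3.8, 52.1 and 716 and 4.0, 27.2 and 523 in unchanged libraries. The single shared library could not be split, so part of any excess can come from it, and at the largest simulated spread unchanged libraries gave overlaps larger than those observed.

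**Figure D3:**
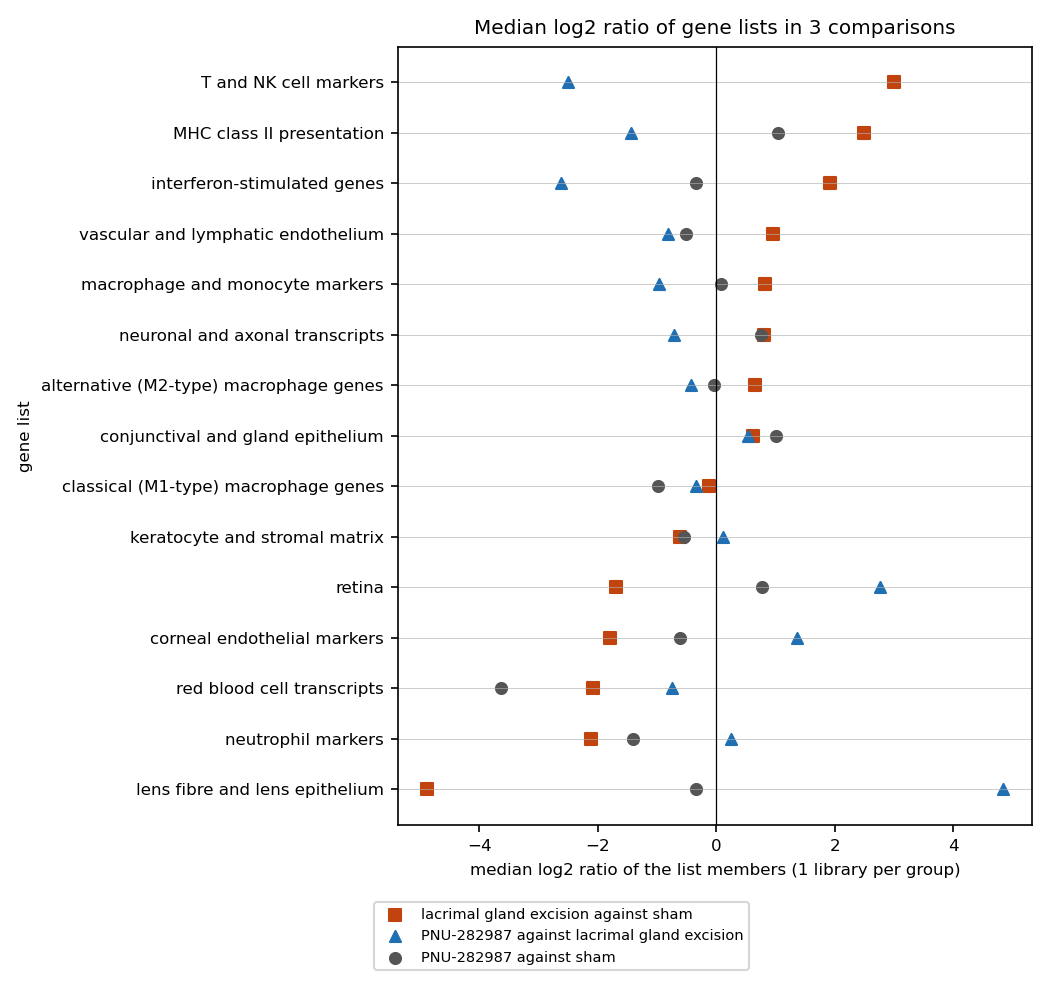
Median log2 ratio (horizontal axis) of gene lists (vertical axis) for excision against sham (squares), PNU-282987 against excision (triangles) and PNU-282987 against sham (circles), for lists whose median stood apart and reached 0.5 in size in at least 1 comparison; each comparison is between single libraries and there are no error bars. Interferon-stimulated genes lie at 1.93, -2.63 and -0.35 and lens genes at -4.88, 4.84 and -0.35, and a point is left out where fewer than 5 members had a ratio.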

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

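The alternative without tissue lists was chosen after the data were seen; the others were planned. No paired analysis was possible because each group has 1 library. Scaling with DESeq2, upper-quartile or total counts, thinning and adding 2 counts left the 6 counts of genes within 1.5 times their main values, and the largest shift of the all-gene median was -0.08 (total counts). Of 1152 list medians recomputed, 1140 lay within their interval or belonged to lists with 5 members, for which no interval was computed. Another 11 moved, each of them with the mean in place of the median. Reversals were counted only for lists that stood apart, and 1 was found. Complement in excision against sham was -0.012 at a count minimum of 50, against 0.45, with fewer members measured. Lists that did not stand apart could also change sign, such as macrophage markers in PNU-282987 against sham (0.07, and -0.007 with total counts). Of 2666 gene ratios, 2645 lay within their counting interval and 21 moved, all under another scaling. With total counts the share of genes in which excision stood apart was 39.5%, with a count minimum of 10 it was 38.85%, with none 38.1% and with 50 it was 45.5%, where PNU-282987 had 28.5%. The correlations of differences were -0.599 and 0.426 at a minimum of 10, -0.679 and 0.380 at 50, and -0.574 and 0.442 with none. Higher and lower genes at a minimum of 50 numbered 337 and 466 for excision against sham, 351 and 459 for PNU-282987 against excision, and 206 and 373 for PNU-282987 against sham, since fewer genes were tested. With no minimum, 948 were higher in excision than in sham, 1240 lower in PNU-282987 than in excision, and 649 higher and 1080 lower in PNU-282987 than in sham. At 4-fold the counts in the same order were 183 and 286, 195 and 245, and 99 and 153, and the shares were 23.3% for sham, 51.0% for excision and 25.7% for PNU-282987. At 1.5-fold they were 1166 and 1281, 1081 and 1582, and 712 and 1376. Of the 68 list and comparison pairs that stood apart, 67 also did with 10 bins (not the mucin list in PNU-282987 against excision, at percentile 97.38) and 53 with the mean, and 8 others stood apart only with the mean, the inflammasome list in 2 of them; median and mean differed in sign for 16 of 128 pairs, 0 of which stood apart. Depth limits genes of few counts such as Chrna7, Il1b, Nos2 and Mmp9, whose intervals span several-fold.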

Other observations

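The tests of explanations for the interferon, lens and goblet cell patterns were chosen only after those results had been seen. Clock genes differed between the libraries. The core activator gene Arntl had 903 counts in sham, 615 in excision and 165 in PNU-282987, which was 5.44-fold lower than sham (95% counting interval 4.61 to 6.46). Per2, whose transcript peaks when Arntl is low, had 518, 988 and 1523 counts, and Per1 had 776, 2225 and 1468. The time of day of collection is not among the sample details used here, so a difference in it was not tested. The clock list stood apart in excision against sham (median log2 0.28) and in PNU-282987 against sham (0.42), and not between the other pair (-0.08). Cell cycle genes did not stand apart in excision against sham (median -0.001), where the replication licensing gene Mcm2 was 2.26-fold higher (2.04 to 2.51) and Cdc20 2.21-fold lower (1.95 to 2.51). Of the mast cell list, 2 members were measured, and Hdc, the histamine-forming enzyme gene, was at low counts of 22, 0 and 1. The list summed to 104.57, 113.81 and 95.46 CPM in sham, excision and PNU-282987, nearly all of it from the other measured member. B and plasma cell genes were at low counts, with Jchain at 27, 24 and 11. Vascular and lymphatic endothelial genes had 4 of 12 members higher and 1 lower in excision than in sham (median 0.95) and 6 lower in PNU-282987 than in excision (-0.82): the lymphatic receptor gene Flt4 had 15, 54 and 8 counts, and Lyve1 is also in the macrophage list. The summed level went the other way, at 81.7, 67.0 and 70.7 CPM in sham, excision and PNU-282987.

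The other lists had small medians, some of which stood apart by percentile. For excision against sham, PNU-282987 against excision and PNU-282987 against sham, medians were -0.06, 0.26 and 0.12 for NRF2 and oxidative stress genes, -0.14, 0.28 and 0.10 for heat shock genes, and 0.12, 0.11 and 0.20 for hyperosmolar response genes. They were 0.23, -0.21 and -0.07 for lipid synthesis, 0.07, -0.24 and -0.18 for nuclear oxidative phosphorylation genes, and -0.18, -0.27 and -0.37 for mitochondrially encoded genes. They were 0.13, -0.04 and 0.23 for toll-like receptors and adaptors, 0.10, -0.07 and -0.03 for matrix metalloproteinases, and 0.13, -0.10 and -0.02 for limbal genes. Pigment cell genes had -0.17, -0.10 and -0.11, sex-linked genes -0.12, -0.07 and -0.18, and interleukins and chemokines 0.26, -0.13 and -0.19. Of these, lists stood apart in excision against sham for heat shock (percentile 0.81), lipid synthesis (98.07), mitochondrially encoded genes (1.98) and interleukins and chemokines (98.76, with 6 of 27 higher and 5 lower, led by Cxcl9, Ccl5, Cxcl2 and Cxcl1). They did in PNU-282987 against excision for NRF2 (99.81), heat shock (99.89), lipid synthesis (1.25), nuclear oxidative phosphorylation (0.06) and mitochondrially encoded genes (2.48), and in PNU-282987 against sham for lipid synthesis (2.13), mitochondrially encoded genes (0.01) and toll-like receptors (99.5), with nuclear oxidative phosphorylation below all random lists. With the mean in place of the median, heat shock (2.69), lipid synthesis (92.0) and mitochondrially encoded genes (19.04) no longer stood apart in excision against sham, nor did NRF2 (97.23), heat shock (96.99), nuclear oxidative phosphorylation (2.92) and mitochondrially encoded genes (8.78) in PNU-282987 against excision, nor toll-like receptors (97.03) in PNU-282987 against sham. The matrix metalloproteinase list had 2 of 13 members higher and 3 lower in excision than in sham: Mmp3 was higher (97, 505 and 116 counts in sham, excision and PNU-282987), and Mmp10 (52, 7 and 18), Adamts1 (354, 120 and 352) and Timp3 (3731, 1462 and 3283) were lower, while Mmp9 had 4, 3 and 1. Fosb and Per1, both induced quickly by stimulation, were highest in the excision library, with Fosb at 105, 318 and 77 counts.

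Interferon-stimulated genes were higher in the excision library than in both others. Scaling, which moves all genes alike, is argued against: the near limit of the list median lay at least 1.585 log2 units from the median of all genes in both comparisons with the excision library. More leukocytes in the excision library could carry part of it, since Cd74, C1qa and Lyz2 (283, 566 and 483 counts in sham, excision and PNU-282987) were higher there and Ptprc, which all leukocytes express, had 6, 36 and 17. The interferon list gained 3774 CPM over sham and the leukocyte lists 256 CPM, a ratio of 14.8, and without the interferon response of those leukocytes this sets no limit. Lacrimal gland excision remains a hypothesis beside any other difference of that sample, and with 1 excision library, for which the labels do not say whether corneas of several mice were pooled, these cannot be told apart.

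Lens and corneal endothelial transcripts were lower in the excision library than in both others. An equal loss of all non-epithelial transcripts is argued against. With excision set against each other library, the stromal list lay at least 1.18 log2 units above the endothelial list. The stromal list was itself lower than in sham (median -0.62), so a loss of unequal size across these tissues is not covered by this test. Less lens and posterior tissue carried over in the dissection of the excision sample is a candidate explanation, because retina genes, which a cornea should lack, were also lower, by a median of at least 1.69 log2 units. Loss of corneal endothelium in the animal was not tested apart from it and stays open for the endothelial genes.

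Goblet and secretory transcripts were higher in the PNU-282987 library than in both others. Over Muc5ac, Gp2, Muc5b, Scgb2b2, Scgb1b2, Esp6, Agr2 and Tff1 the lowest lower limit of the log2 counting interval against either other library was 3.117. These genes were named because they were called, which requires an interval that excludes equal levels. The selection thus largely fixed this test of counting noise, and no conclusion is drawn from it. Conjunctival tissue in the PNU-282987 sample may account for it: of the keratin genes Krt13, Krt4, Krt19 and Krt7, 3 were higher than in both other libraries, and Krt19, at 2942, 6819 and 6825 counts in sham, excision and PNU-282987, was not higher than in excision. The sham library, with 1 count of Muc5ac, held 78979, 3013, 2942 and 2679 counts of Krt13, Krt4, Krt19 and Krt7, so these keratins do not mark goblet-bearing tissue alone, which keeps this open. The conjunctival and gland list was also above sham in the excision library (median 0.61, with Agr2 at 49 and 133 counts and Muc5ac at 1 and 11). Other secretory genes were not higher there, with Spdef at 22 and 4 counts, Muc5b at 1 and 0 and Gp2 at 5 and 4. Part of this list was thus above sham in both libraries, while the large rise of the secretory genes was seen in PNU-282987 alone. An effect of the eyedrops on secretory cells is confounded with the single PNU-282987 library and was not tested.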
